A study of Drosophila melanogaster with 4 samples.

How the data were processed

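GRO-seq libraries of S2 cells were compared between 2 groups, LacZ-RNAi and Fcp1-RNAi, with 2 biological replicates each, as the labels state. Per the labels' protocols, the nuclei ran on for 10 minutes at 30 °C with bromouridine triphosphate. The RNA was hydrolysed to an average of 100 to 150 nt, purified in 2 immunoprecipitations, tailed with adenines, reverse transcribed, circularised and amplified in 12 to 15 PCR cycles. Per the submitters' processing notes, reads were handled with cutadapt and Bowtie and placed on dm3. Their versions and settings are not given in the sources used here. Base hydrolysis places a read's 5' end within about a fragment of where the polymerase stood, so positions near a start are blurred. PCR without molecular identifiers lets 1 molecule give several reads, and intervals and floors cover counting error only.

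The deposited files hold 1 aligned read of 26 nt per line, with its position, strand and a count of 1, so the values the authors deposited are raw counts and were not normalised. Everything else was computed here from those lines. No read sequence was found at more than 1 position. Reads from near-identical gene copies may thus be missing, which matters for multi-copy families. The files' coordinates were used as they are. The annotation at hand is for another release and was not used, and no coordinate was converted.

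The design fixed before the data were examined named genes, with strand-specific 1 kb bins as the fallback where no annotation of the files' release was at hand. The bins are therefore the main test. Reads were counted by 5' end and strand. edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, group only, two-sided, Benjamini-Hochberg adjusted p under 0.05) tested 49213 of 149038 bins with a read. All called bins are named, which is the naming rule for bins applied to those past the threshold. Tests downstream of gene ends, of gene lists by name, of cell type markers and of the targeted gene were not analysed here.

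Features chosen after seeing the data stood in for genes. Transcription units are runs of at least 3 windows of 500 nt with at least 10 pooled read positions, with gaps of at most 1 window. Positions were counted once per library and summed over the libraries, so a position shared by several libraries counted several times. Start sites needed at least 40 positions, counted in the same way, in the start window and at least 40 from 200 to 1200 nt downstream. They also needed at most 0.25 of the start window's density in the 500 nt upstream, and a spacing of 1500 nt. Protein family signatures were searched in the translated consensus of the reads, which covered 43140608 positions. A family was kept where at most 10% of its oriented sites lay antisense to transcription, and counts were taken from 1000 nt on each side. Sites for the Fcp1 phosphatase signature were not found among covered sequence. Start, antisense and signature counts used the library factors of the bin test. Lists of at least 5 windows were tested with limma 3.58.1 camera at a preset correlation of 0.01, on log CPM.

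Pausing was tested as the interaction of region and group over the start and downstream counts of each library. Fold changes are Fcp1-RNAi over LacZ-RNAi on the log2 scale. Within-batch values are the ratio of the libraries with the same replicate number, with 0.5 added to each count. P-values reflect the spread between 2 replicates per group. No spike-in was used here, so a change common to all transcription would not be seen.

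Depth ranged from 1416442 to 4911167 reads. The share of reads at distinct positions was 74.7% and 77.0% in replicate 1 and 69.4% and 70.1% in replicate 2 of LacZ-RNAi and Fcp1-RNAi. Tests were tried on simulated data with 200 changed features drawn from the libraries' means. With replicate number as a term, they called 46.5% of 99 bins changed by 2-fold and 93.3% of 89 changed by 4-fold, with 7 false calls. For units this was 86.6% of 97 and 96.9% of 96, with 4 false calls. The test without that term called fewer in each case.

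Alternatives were DESeq2 1.42.0 size factors and Wald test, library totals, no low-count filter, identical alignments counted once, thinning to 1416442 reads, scaling to mitochondrial reads, other windows, start-site windows with their own TMM factors, the replicate number as a block, and each library left out. Added after seeing the data were leaving out reads with at least 25 of 26 bases A or C, a GC correction of units, and combinations with the block. Not planned beforehand for antisense windows were DESeq2 size factors and Wald test, library totals, and no low-count filter. Nor were thinning, own TMM factors and identical alignments counted once for those windows. For the count of family lists changed, identical alignments counted once was also not planned. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for counting.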

Results

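Nascent transcription was measured in Drosophila melanogaster S2 cells, an established embryonic cell line, after RNA interference (RNAi) against Fcp1 or against LacZ. Fcp1 is a phosphatase of the C-terminal domain of RNA polymerase II. LacZ is a bacterial gene with no counterpart in the fly, so the LacZ-RNAi cells served as the control. The assay was global run-on sequencing (GRO-seq), in which engaged polymerases extend their transcripts in isolated nuclei with bromouridine, and the labelled RNA is purified and sequenced. There were 2 biological replicates per group. LacZ-RNAi replicates 1 and 2 held 1646667 and 4896519 aligned reads, and Fcp1-RNAi replicates 1 and 2 held 1416442 and 4911167. All coordinates are in genome release dm3, 1-based. No gene annotation of that release was used here, so regions are given by position and strand, and exons, introns and gene names were not assigned. The reads of the Fcp1 gene itself were therefore not analysed here, and the RNAi was not checked on its target.

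The labels name no batches, but the files of the libraries differed by replicate number. Replicate 1 of both groups was shallower and began with adenine in 61.1% (LacZ-RNAi) and 60.1% (Fcp1-RNAi) of reads, against 52.5% and 53.2% in replicate 2. Libraries with the same number are therefore called a batch here, which is read from the files and not from the design. Each change is given for all libraries together and within each batch. Levels are given as CPM, read counts scaled by library size and TMM factor.

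The main comparison asked which transcribed regions differed between Fcp1-RNAi and LacZ-RNAi cells. On the plus strand of chromosome X, bin 460001 to 461000 was 10.7-fold higher in Fcp1-RNAi cells, and its reads were spread over 179 positions. It held 37.6 ± 3.31 CPM in Fcp1-RNAi (SD, n = 2) and 3.53 ± 1.27 in LacZ-RNAi (SD, n = 2). The log2 change was 3.26 (SE 0.34, edgeR quasi-likelihood test, adjusted p = 0.0237), with 3.77 in batch 1 and 2.96 in batch 2. Of 49213 strand-specific 1 kb bins tested, 3 were higher and 3 lower in Fcp1-RNAi at an adjusted p under 0.05. With libraries scaled to mitochondrial reads the split was 7 higher and 4 lower, but each library held only 321 to 726 such reads.

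Of the other 5 called bins, 4 rested mostly on a single position. Bin 8971001 to 8972000 on the plus strand of X was higher in Fcp1-RNAi, at 26.9 ± 8.23 against 1.18 ± 0.18 CPM (SD, n = 2 each), with 81.7% of its reads at 1 position. Bin 13886001 to 13887000 on the same strand had no read in either LacZ-RNAi library and 239 in the Fcp1-RNAi libraries. It was at least 82.0-fold higher against a floor of 3 reads over the LacZ-RNAi group, and 98.7% of its reads lay at 1 position. Lower in Fcp1-RNAi were bin 18039001 to 18040000 on the plus strand of X, with 1209 reads in LacZ-RNAi and 5 in Fcp1-RNAi, and bin 20208001 to 20209000 on the minus strand of 2R, with 331 reads against 0. The 2R bin was at least 107-fold lower against the same floor. Of their reads, 99.2% and 100.0% lay at a single position. Bin 3464001 to 3465000 on the plus strand of Uextra, an assembly of unplaced sequence, was also lower, with 123 reads in LacZ-RNAi and 5 in Fcp1-RNAi over 23 positions. These floors cover counting error only, since reads were amplified without molecular identifiers. With identical alignments counted once, 1 bin was higher and 0 were lower (300 and 212 at an unadjusted p under 0.05). The bin at 460001 on X lost its call when libraries were thinned to equal depth (log2 change 2.90, adjusted p = 0.219). Leaving out single libraries raised the counts to between 32 and 103 higher and between 11 and 62 lower. In data simulated from these libraries, the test with no batch term called 0% of 99 bins changed by 2-fold and 0% of 89 changed by 4-fold.

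Longer stretches of transcription were compared next. Reads were joined into 6583 transcription units with a median length of 5000 nt, which held 94.7% to 95.8% of each library's reads. Among 5027 units with a mean of at least 50 reads per library, 5 were at least 2-fold higher in Fcp1-RNAi in both batches, and 0 were at least 2-fold lower in both. These 5 units were chosen after their values were seen. Another 2 units changed by at least 2-fold in opposite directions in the batches. At 1.5-fold the counts were 17 higher in both batches, 5 lower in both and 5 in opposite directions.

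The unit that contains the called bin runs from 459501 to 465000 on the plus strand of X. It went from 11.5 ± 4.36 CPM in LacZ-RNAi to 104 ± 15.5 in Fcp1-RNAi (SD, n = 2 each). Its log2 change was 3.41 in batch 1, 2.96 in batch 2 and 3.07 (SE 0.26) for all libraries. That change passed DESeq2's Wald test (adjusted p = 9.4e-13) but not edgeR's quasi-likelihood test (adjusted p = 0.194). Reads at its start site, position 459721, had a log2 change of 2.29 (SE 0.53, edgeR adjusted p = 1.000).

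The unit from 22702001 to 22738500 on the plus strand of 3R was the longest of the 5, at 36500 nt, and had the most reads. It held 248 ± 36.8 CPM in LacZ-RNAi and 622 ± 105 in Fcp1-RNAi (SD, n = 2 each). The log2 change was 1.30 in batch 1, 1.34 in batch 2 and 1.32 (SE 0.17) for all libraries (DESeq2 adjusted p = 2.9e-07, edgeR adjusted p = 0.574). It contained 2 start sites. The window at 22707501 went from 148 ± 9.60 to 308 ± 12.6 CPM (SD, n = 2 each), and the window at 22702401 from 6.54 ± 0.89 to 6.25 ± 2.44 (SD, n = 2 each). Their log2 changes were 1.05 (SE 0.25) and 0.01 (SE 0.41), and neither passed edgeR's test.

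On the plus strand of 2R, the unit from 17409501 to 17412000 went from 11.9 ± 2.47 to 44.2 ± 1.59 CPM (SD, n = 2 each). Its log2 change was 1.71 in batch 1 and 2.07 in batch 2 (1.94 for all libraries, SE 0.25). On the minus strand of 2L, the unit from 2371501 to 2376000 went from 86.6 ± 12.6 to 181 ± 23.1 (SD, n = 2 each), with log2 changes of 1.05 in batch 1 and 1.08 in batch 2. With identical alignments counted once the change of the 2L unit was 0.67, which is under 2-fold. Both passed DESeq2's Wald test (adjusted p = 0.0325 each), and neither passed edgeR's test (adjusted p = 0.574 and 1.000). A further X unit, from 1058501 to 1066000 on the plus strand, had 20.9 ± 1.93 and 63.8 ± 21.0 CPM (SD, n = 2 each). Its log2 changes were 2.00 and 1.14 in the batches, and it passed neither test (DESeq2 adjusted p = 0.0841). At the start sites of these 3 units, positions 17409881, 2374481 and 1058961, the log2 changes were 2.10 (SE 0.34), 1.15 (SE 0.30) and 1.09 (SE 0.74), with no edgeR call. The X start site went in opposite directions in the batches, with log2 changes of 1.65 and -0.17. In the 2R and 2L units the start window held most of the unit's reads in each library. In Fcp1-RNAi replicate 2 these were 145 of 203 reads and 601 of 777, so both changes lie largely at the start.

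**Figure D1:**
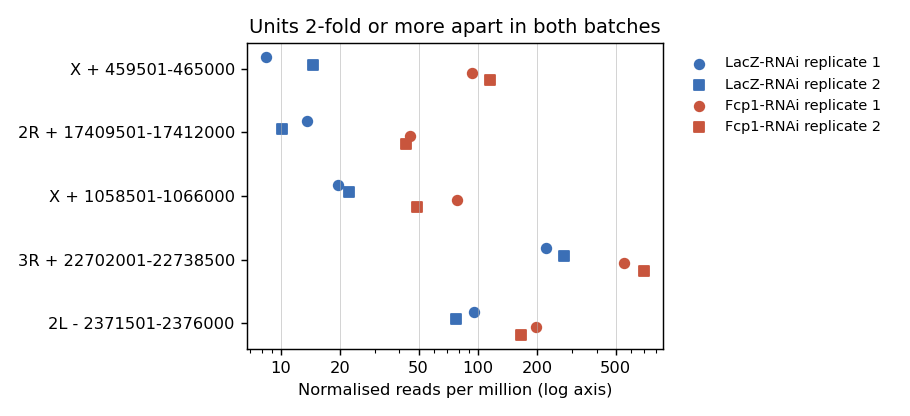
Normalised CPM (log axis) of the 5 units that were at least 2-fold higher in Fcp1-RNAi in both batches, named by chromosome, strand and position in dm3; each point is 1 library. In each unit both Fcp1-RNAi libraries lie above both LacZ-RNAi libraries, from 92.8 and 115 against 8.45 and 14.6 in the top unit to 198 and 165 against 95.5 and 77.7 in the bottom one.

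Most units differed little. Of the 5027 units, 92.2% changed by less than 0.5 on the log2 scale in both batches. Over all 6456 units tested, the median log2 change was -0.01, with quartiles at -0.11 and 0.10 and a median SE of 0.20. edgeR called 0 units higher and 0 lower, with 36 higher and 28 lower at an unadjusted p under 0.05. By chance 322.8 units would fall under 0.05, so the test with no batch term was conservative. With replicate number as a block, edgeR called 89 units higher and 63 lower. Without the block, DESeq2's Wald test called 4 higher and 0 lower. In simulated data the edgeR test with no batch term found 28.9% of 97 units changed by 2-fold and 78.1% of 96 changed by 4-fold. A 2-fold change in a unit could thus pass without a call. In the real libraries the same test did not call the X unit at 459501, which was 8.39-fold higher (edgeR adjusted p = 0.194). Larger changes could therefore pass without a call too, and the simulated rates may be too high for these data.

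**Figure D2:**
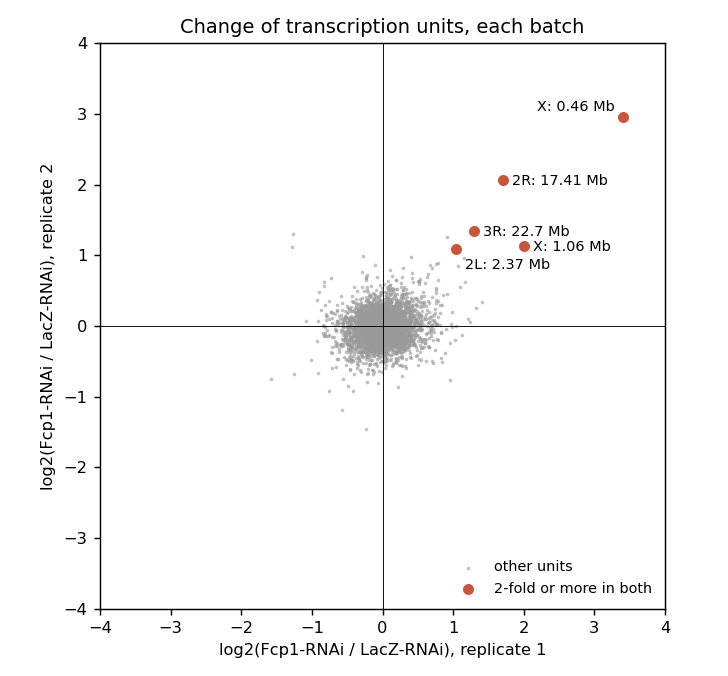
Log2 ratio of Fcp1-RNAi to LacZ-RNAi in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for 5027 transcription units with a mean of at least 50 reads per library. Grey points are other units and red points the 5 units at least 2-fold higher in both, labelled with chromosome and start; most units lie near 0 on both axes.

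The series title ties Fcp1 to efficient transcription of heat shock genes, and the labels name no heat treatment. Heat shock genes were not looked up by name here. In their place, windows were taken around protein signatures of the Hsp70 and Hsp90 chaperone families, found by translating the sequence assembled from the reads. The families include members made at normal temperature as well as heat-induced ones. Copies that share reads may be missing, because no read sequence was placed at more than 1 position. Of 6 such windows, 0 passed edgeR's test, either over all 675 signature windows or adjusted over the list alone. None of the 6 was higher in both batches, and 2 were lower in both. With replicate number as a block, 1 of them was called lower and 0 higher. Without the block, 5 of the 675 windows had an unadjusted p under 0.05 in edgeR's test. That is fewer than by chance, so this test was conservative too. No changes were simulated for signature windows.

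The largest difference was in an Hsp70-family window at 19881247 to 19883810 on the minus strand of 3R. It held 306 ± 146 CPM in LacZ-RNAi and 173 ± 23.9 in Fcp1-RNAi (SD, n = 2 each). The log2 change was -0.81 (SE 0.30, edgeR adjusted p = 0.993 over all windows and 0.114 adjusted over the list alone). The batches differed, with -1.39 in batch 1 and -0.10 in batch 2, where LacZ-RNAi replicate 1 lay apart at 409 against 203, 156 and 190 in the other libraries. The Hsp70-family window at 11069106 to 11071669 on the plus strand of 3R had 561 ± 255 and 576 ± 42.9 CPM in LacZ-RNAi and Fcp1-RNAi (SD, n = 2 each). Its log2 change was -0.29 in batch 1 and 0.52 in batch 2. The Hsp70-family windows at 10141155 to 10143880 on 2R and at 11696953 to 11699954 on X, both on the minus strand, had log2 changes of -0.10 (SE 0.23) and 0.09 (SE 0.21). The Hsp90-family window with the most reads, at 3193574 to 3195573 on the plus strand of 3L, held 906 ± 76.8 in LacZ-RNAi and 853 ± 152 in Fcp1-RNAi (SD, n = 2 each). The other Hsp90-family window, at 23774127 to 23776126 on the plus strand of 3R, held 324 ± 39.0 and 296 ± 6.92 (SD, n = 2 each). Across the 6 windows the median log2 change was -0.09, with limma camera p = 0.241 (adjusted p = 0.820 over 5 lists, 0.988 with an estimated correlation). The median was -0.26 in batch 1 and 0.12 in batch 2, and it became 0.10 without LacZ-RNAi replicate 1 (limma camera adjusted p = 0.514) and -0.31 without LacZ-RNAi replicate 2 (limma camera adjusted p = 0.0630).

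**Figure D3:**
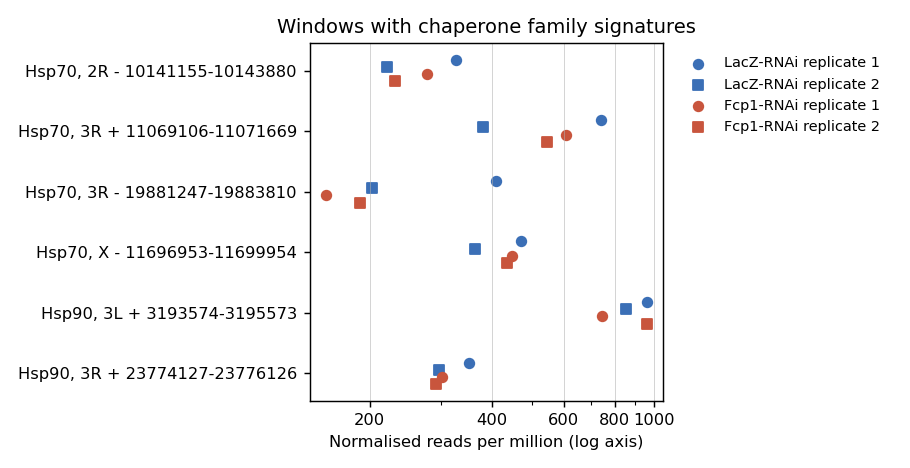
Normalised CPM (log axis) in the 6 windows with an Hsp70 or Hsp90 family signature, named by chromosome, strand and position in dm3; each point is 1 library. LacZ-RNAi replicate 1 has the highest value in every window, by a margin of 961 to 960 over Fcp1-RNAi replicate 2 in the Hsp90-family window on 3L.

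Other protein families were compared in the same way. Of 13 DEAD-box RNA helicase windows, which mark enzymes that unwind RNA, 1 was higher and 1 lower in both batches. Of 11 windows of ubiquitin-conjugating enzymes, 2 were higher and 4 lower in both, and of 10 AAA ATPase windows 2 and 3. The 50 serine/threonine protein kinase windows divided into 11 higher and 18 lower in both batches. Their median log2 changes were -0.05 for the helicases, -0.10 for the ubiquitin-conjugating enzymes, 0.03 for the AAA ATPases and -0.02 for the kinases. The DEAD-box window with the most reads, at 5983310 to 5985309 on the plus strand of 2L, held 166 ± 71.1 in LacZ-RNAi and 162 ± 29.5 in Fcp1-RNAi (SD, n = 2 each). The ubiquitin-conjugating enzyme window with the most reads, at 541004 to 543003 on the minus strand of 2L, held 171 ± 2.69 and 156 ± 12.2 (SD, n = 2 each). The kinase window with the most reads, at 569299 to 571298 on the plus strand of 3L, held 121 ± 5.79 and 127 ± 13.7 (SD, n = 2 each). The cyclophilin window with the most reads, at 18532038 to 18534037 on the minus strand of 2R, held 278 ± 41.4 and 299 ± 53.2 (SD, n = 2 each). Of the 105 windows in the 11 families kept, 0 passed edgeR's test and 1 had an unadjusted p under 0.05. None of the 5 lists with at least 5 members, chaperones included, passed camera. The smallest camera adjusted p was 0.820, for the chaperone and kinase lists.

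Promoter-proximal polymerase was compared at 7237 start sites found from the reads. These sites were chosen from the same pooled reads for a dense start window, few reads upstream and enough reads downstream. That distinct read positions peaked 0 to 50 nt past the called site in all 4 libraries thus follows in part from that choice. It is not a measured pause position. The 50 nt before the called site already held 6.37 and 3.86 positions per site, scaled for depth, in LacZ-RNAi replicates 1 and 2. In Fcp1-RNAi they held 6.43 and 3.73, so the called starts are approximate. Windows from 50 nt upstream to 150 nt downstream held 24.1% ± 1.06 of reads in LacZ-RNAi and 22.8% ± 1.95 in Fcp1-RNAi (SD, n = 2 each). This difference is within the spread between replicates, which includes that between the batches. The share was lower in Fcp1-RNAi in both batches, at 24.1% against 24.8% in batch 1 and 21.4% against 23.3% in batch 2. No test was made on these shares. With identical alignments counted once the shares were 14.8% and 12.2% in LacZ-RNAi replicates 1 and 2, and 15.0% and 11.1% in Fcp1-RNAi. The direction turned in batch 1, but such shares depend on depth. In batch 1 LacZ-RNAi had 1646667 reads and Fcp1-RNAi 1416442, so the turn is not read as a result. The median log2 change of 7214 windows was -0.11, with -0.04 in batch 1 and -0.15 in batch 2. edgeR called 0 windows higher and 0 lower (14 higher and 57 lower at an unadjusted p under 0.05, or 33 and 30 with the windows' own TMM factors), and DESeq2's Wald test likewise called 0.

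The ratio of start-site reads to reads 200 to 1200 nt downstream, a measure of pausing, had a median log2 change of -0.14 over 7237 sites. It was -0.03 in batch 1 and -0.21 in batch 2. By density the start window exceeded the downstream window by 6.71 and 6.92 times in LacZ-RNAi replicates 1 and 2, and by 6.70 and 6.11 times in Fcp1-RNAi. Sites were chosen for a dense start window and at least 40 pooled positions downstream, which left out starts with few downstream reads. The size of these ratios is thus not read as a result, only their differences between libraries. With identical alignments counted once these ratios were 3.74 and 3.47 in LacZ-RNAi and 3.89 and 3.10 in Fcp1-RNAi, which is higher in Fcp1-RNAi in batch 1. Ratios counted this way also depend on depth, which differed between the libraries, so that turn is not read as a result. edgeR's interaction test called 0 sites higher and 0 lower (19 and 66 at an unadjusted p under 0.05), as did DESeq2. Upstream antisense reads, 1 to 500 nt from 2401 of these start sites, had a median log2 change of -0.06, with 0.02 and -0.10 in the batches. edgeR called 0 windows in either direction (8 higher and 12 lower at an unadjusted p under 0.05), and DESeq2 called 0. By chance 360.7 start-site windows, 361.85 ratios and 120.05 antisense windows would fall under 0.05. Fewer did so in each case, so these tests were conservative too. With replicate number as a block, edgeR called 16 start-site windows higher and 69 lower. For antisense windows the block gave 5 and 3, and for ratios 0 and 4. With identical alignments also counted once, the counts were 2 and 0, 0 and 0, and 0 and 10. For start-site windows and ratios the simulated 2-fold and 4-fold changes were called in 0% of cases with no batch term, so this test would have missed such changes at single sites.

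**Figure D4:**
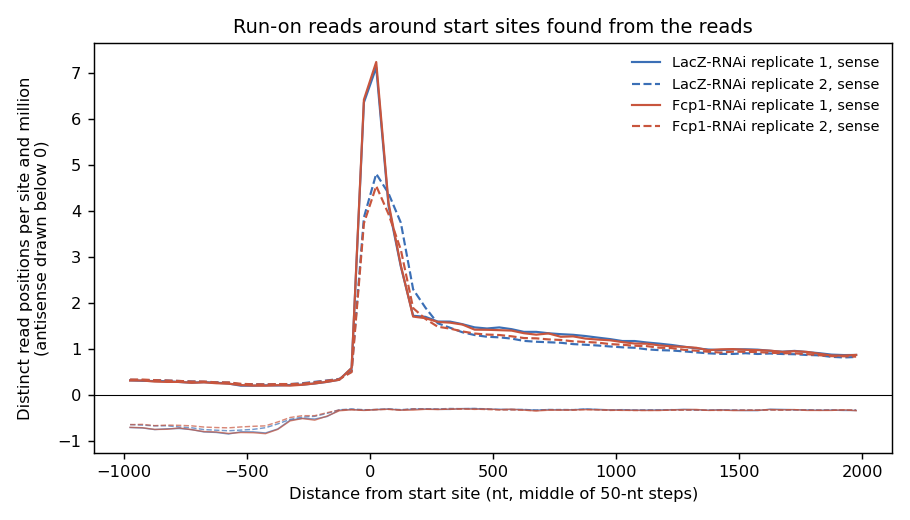
Distinct read positions per site in each library, scaled for depth, in 50-nt steps around 7237 start sites, with antisense drawn below 0. The sites were chosen from the same pooled reads for a dense start window, so a peak near 0 follows in part from that choice. The peak height is 7.13 and 7.25 in replicate 1 and 4.81 and 4.55 in replicate 2 of LacZ-RNAi and Fcp1-RNAi; each position counts once, so heights are not compared between libraries of different depth.

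Shares of reads were also taken by chromosome. Chromosome X held 12.5% and 12.6% of reads in LacZ-RNAi replicates 1 and 2, and 12.7% and 12.8% in Fcp1-RNAi. The mitochondrial genome held 0.0218% and 0.0133% in LacZ-RNAi, and 0.0227% and 0.0148% in Fcp1-RNAi. No test was made on these shares.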

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

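Unit tests, removal of A/C-only reads, GC correction and combinations with the block were chosen after the results were seen. For antisense windows, only the block, the left-out libraries and the shorter window were planned among the alternatives. Identical alignments counted once was not planned for the count of family lists changed. The bin counts of 3 higher and 3 lower were the same with DESeq2 size factors and library totals. Higher and lower bins numbered 6 and 4 with DESeq2's Wald test, 74 and 31 without the low-count filter, 1 and 0 with identical alignments counted once, 1 and 2 after thinning, 7 and 4 with mitochondrial scaling, and 2 and 1 without A/C-only reads. Single libraries left out gave 32 to 103 higher and 11 to 62 lower, where the lone library was assumed to vary like the other group. The cause was not tested.

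Same-numbered libraries deviated together (correlation 0.61 across units). Libraries correlated at 0.982 and 0.991 within a number, against 0.971 and 0.972 within a group. With replicate number as a term, the common biological coefficient of variation fell from 15.6% to 5.27%. These values go with the numbers being batches. There were only 2 pairs and the labels state no pairing, so the block was kept as an alternative. With the replicate block, bins numbered 157 higher and 89 lower, units 89 and 63, start-site windows 16 and 69, antisense windows 5 and 3, and pausing ratios 0 and 4. No family list changed with the block, though 1 chaperone window was then lower. With block and identical alignments counted once, they were 94 and 19, 69 and 35, 2 and 0, 0 and 0, and 0 and 10. Units numbered 94 and 56 with block and GC correction, and 6 and 0 with block and DESeq2's Wald test. The block reversed the failed edgeR calls of all 5 named units, with adjusted p = 6.4e-80 (X 459501), 2.4e-62 (3R 22702001), 1.3e-21 (2L 2371501), 2.8e-19 (2R 17409501) and 2.8e-15 (X 1058501). With block and DESeq2 the last of these had an adjusted p = 0.0152.

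Without the block, units numbered 4 higher with DESeq2's Wald test and 1 with mitochondrial scaling, which moved the median unit to -0.12. That scaling rests on 359 and 649 mitochondrial reads in LacZ-RNAi replicates 1 and 2, and 321 and 726 in Fcp1-RNAi. Its factors thus carry counting error, and the shift is not read as a result. Leaving out libraries gave 0 to 1 higher and 0 lower units, 0 to 4 higher start-site windows, 0 to 2 higher antisense windows and 0 to 1 lower ratios. Antisense windows numbered 1 higher without the filter. The chaperone median ranged from -0.31 to 0.10 over left-out libraries and reversed to 0.10 without LacZ-RNAi replicate 1. Among called bins, X 460001 (log2 change 2.90), X 8971001 (4.21) and Uextra 3464001 (-4.57) lost their calls after thinning, which leaves fewer reads, and the Uextra bin also with alignments counted once (-2.49). The bins X 8971001, X 13886001, X 18039001 and 2R 20208001 then had too few reads to be tested, so only X 460001 kept its call. Without A/C-only reads the last 3 of these were not tested either. The 5 units kept their direction in all 17 alternatives. With identical alignments counted once their log2 changes were 2.74 (X 459501), 1.57 (2R 17409501), 1.51 (X 1058501), 1.31 (3R 22702001) and 0.67 (2L 2371501), the last under 2-fold. Scaling to Pol III genes, gene-body start, gene model, overlapping genes, downstream windows and summed Hsp70 copies need annotation and were not run.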

Other observations

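The tests on A/C-only reads, on piles split by the reads beside them, on crossed pairs of libraries, on identical reads in the X unit, on the order of its libraries and on genome blocks were chosen after the results were seen. The tests on reads beside the piles, on piles of any other pair, on neighbouring units and on the agreement of the batches were written before their results, but the readings of the count of other piles, of all reads beside piles and of the batch agreement were changed afterwards.

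Unplaced heterochromatin of the Y chromosome (YHet) had 11 and 31 reads in LacZ-RNAi replicates 1 and 2, and 36 and 53 in Fcp1-RNAi. As shares these were 3.80-fold and 1.70-fold higher in Fcp1-RNAi within the batches. The heterochromatic parts of X (XHet) had ratios of 0.948 and 0.922, and chromosome 4 had ratios of 1.01 and 0.974. No test was made on these shares.

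The unit at 459501 to 465000 on the plus strand of X stood out from its surroundings. With identical alignments counted once its log2 change was 2.74, so repeated reads of the same molecules do not account for it. The 5 other units within 50 kb had a median log2 change of 0.0219, from -0.16 to 0.45, which argues against more DNA copies of the surrounding region. That both Fcp1-RNAi libraries (2 of 2) lay above both LacZ-RNAi libraries follows from how the unit was chosen and supports no explanation. A response to loss of Fcp1 cannot be told apart from another effect of the RNA used for the interference, since 1 treatment was compared.

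Reads piled at single positions in the libraries of one RNAi group were found at 17 positions, 7 in LacZ-RNAi and 10 in Fcp1-RNAi. Each had at least 10 reads in both libraries of the group and at most 5% of its reads elsewhere. Of same-strand reads within 500 nt but off the pile, 50.2% were in the group with the pile, but nearly all of them lay beside 7 piles. Beside these 7 the share was 50.0% (47.3% to 57.7% per pile), which argues against a change in transcription there. The other 10 piles had 20 such reads in all, 14 of them (70%) in the group with the pile, and 5 had none. The rule written beforehand also counted a near lack of such reads against a change, but for all piles together. It was not applied to this part, chosen by its few reads. These reads are too few to decide, so a change in transcription stays open for the 10 piles. Crossed pairs of libraries, one from each group and batch, held 0 such piles, which argues against by-products that vary by library alone, though this test was added once its count was known. Low-complexity by-products of library making may account for part of them. Of their reads, 65.7% were made of A and C alone, against 0.00118% in piles found in all libraries, but 9 of the 17 piles held no such read. The share was 81.4% in the LacZ-RNAi piles and 39.2% in the Fcp1-RNAi piles. Pairs within a batch held 1471 piles with no A/C-only read. By the rule written beforehand that count favoured by-products that vary by library whatever the group. It was taken as undecided after it was seen, because the batches differ in depth and base composition, which may affect such a count. That was not tested. Of these piles 81 were specific to batch 1, the shallower one, so depth alone does not account for those.

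The log2 ratios of the batches were weakly related across the 5027 units, with r = 0.20 (bootstrap 95% interval 0.14 to 0.28) and Spearman's rho of 0.12. Units are not independent replicates. Without the 20 units of largest change r was 0.13. The relation was 0.199 after a trend with GC content was removed, 0.185 with identical alignments counted once and 0.205 after a trend with transcription level was removed, with lower interval ends of 0.131, 0.120 and 0.137. Resampling 262 genome blocks of 500 kb gave lower ends of 0.133, 0.120 and 0.140. All lie above the 0.05 written beforehand as the most that would remain, so none of these is the whole cause. The correlations themselves are above the 0.15 written beforehand for ruling a cause out, but the lower ends do not reach it. Using 0.05 for the lower ends was chosen after the values were seen. Removing the trend with transcription level did not lower r (0.205 against 0.202), so no part of that trend was seen. A smaller part in the relation stays open for GC content and repeated reads. So do a response to the RNAi and other differences between the treatments common to both batches.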
